A study of Mus musculus with 6 samples.

How the data were processed

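Total RNA from the dissected left and right EC was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 3 per side, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and every value column of the tables matched 1 sample. The authors deposited a table of log2 signals for 41345 rows and 6 arrays. Its log2 scale was inferred from the values, which run from 2.36 to 14.1 with medians of 7.24 to 7.28, and the summarization and normalization behind it are not given in the sources used here. Of the rows 803 held values identical to an earlier row, and all rows were kept. The rows carry numeric IDs that the sources used here do not pair with genes. The authors also deposited a table of all genes with a p-value and a signed fold per row, and a shorter table of genes past a p-value of 0.01, per the file headers. A signed fold is never between -1 and 1, and a negative fold is minus the reciprocal ratio. Ingenuity iReport was used for the analysis, per the series description, but the test behind the deposited p-values and its normalization are not given in the sources used here.

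The per-array values were tested as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, side as the only term), with Benjamini-Hochberg adjustment over all rows at a threshold of 0.05. Rows with a mean over the 6 arrays above the median of row means were counted as detected. The 95% interval of each difference was set against a bound of 1.5-fold. On a simulated table of 41345 independent rows, with spreads drawn from the fitted variance model, 38% of rows changed by 0.5 on the log2 scale were called. The share was 94% at 1, 92% at 2 and 98% at 4, with 10 false calls. All sizes were present in the same table, with 50 rows changed at each. Rows with large changes ease the adjusted threshold for the others, so these shares may be lower where fewer rows differ. Of unchanged rows 5.15% had an unadjusted limma p under 0.05. Rows that vary together were not simulated, so these shares need not hold for them.

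Because the rows have no names, named genes and gene lists rest on the authors' deposited table, a departure from the design fixed before the data were examined, which had planned limma values per gene and camera. Its signed folds were turned into log2 folds, left over right. Its 20414 rows gave 18746 genes, of which 17944 had an identifier in the GRCm38.p6 gene table. Of the genes 1070 had several rows, and these were averaged as log2 folds and signed z values, so that their p comes from the mean z and is not the deposited one. Other p-values of single genes are the authors' p-values as deposited, and their adjusted p is a Benjamini-Hochberg adjustment made here.

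The 29 gene lists (cell types, neighbouring regions, layers, activity, synapse and channels, laterality, disease, handling, metabolism and sex chromosomes) were fixed before the data were examined. The 28 lists with at least 5 measured genes were tested with limma's cameraPR on signed z values of the deposited p-values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. cameraPR asks whether the genes of a list rank apart from the other genes, and it uses no spread between arrays. No estimated correlation, fry or leave-one-out value can be had for named genes without per-array values. On independent simulated z values of 18000 genes, a list of 8 shifted by -1.5 had a p of 0.000138 by limma's cameraPR. Of unshifted lists 3.7% had a cameraPR p under 0.05. Correlated genes were not simulated, so this share does not carry over to lists whose genes correlate.

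The rule for named genes took all genes of the cut-off table, 8 genes per direction by smallest p because no gene passed adjustment, up to 3 members of each list by smallest p, and a set of reference genes. A gene that the rule names is not reported here. Its condition that the arrays of the sides do not overlap, and that a row is detected, could not be applied to named genes. Alternatives covered normalization, filtering, the replicate number as a block, variance models, array weights, leaving out each array, and for lists the preset correlation and the statistic. Figures were drawn with matplotlib 3.10.9.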

Results

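Gene expression was measured in the left and the right entorhinal cortex (EC), the cortical area that links the neocortex with the hippocampus, of wild-type C57BL/6 mice aged 6 months. Each side was represented by 3 Affymetrix Mouse Gene 2.0 ST arrays described in the labels as biological replicates, 6 arrays in all. The labels do not state whether a left and a right sample came from the same mouse, so each limma p-value measures the spread between these samples. The test behind the deposited p-values is not given in the sources used here. The per-array table held 41345 rows of log2 signal with medians from 7.24 to 7.28 per array, and pairs of arrays correlated at 0.995 to 0.996 across rows. For arrays the precision is limited by their number, 3 per side. Per-array values had no gene names, whereas named genes had only a fold and a p-value in the authors' deposited table, so named genes below carry no replicate mean or SD.

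The comparison asked which transcripts differ between the left and the right EC. Among the genes of the fixed lists, those listed for the choroid plexus, the epithelium that makes cerebrospinal fluid, had the largest folds, all higher on the right. Positive folds were read as higher on the left, which is likely the coding because the title line of the authors' deposited table names left versus right and the largest differences lay on the right side in both tables. In the authors' deposited table Ttr, the thyroid hormone carrier transthyretin, was 5.59-fold higher on the right (deposited p = 0.0392). Kl, encoding klotho, was 2.82-fold higher on the right (deposited p = 0.0268), the channel Kcnj13 2.29-fold (deposited p = 0.0969), the chloride channel protein Clic6 2.07-fold (deposited p = 0.0302) and the secreted antagonist Sostdc1 2.01-fold (deposited p = 0.0213) in the authors' deposited table. No gene passed adjustment over the 18746 genes of that table, where the smallest adjusted p was 0.509.

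The fixed choroid plexus and ependyma list had 8 genes in the authors' deposited table, and all 8 were higher on the right, with a median log2 fold of -1.03. Of these, 5 had a deposited p under 0.05, 0 passed when adjusted over the list alone and 0 when adjusted over all genes. As a group the list was higher on the right than the other genes by cameraPR with a preset correlation of 0.01 (adjusted p = 2.16e-05). The call held with a preset correlation of 0.2 (adjusted p = 0.027 by cameraPR) and was lost with a preset correlation of 0.5 (adjusted p = 0.446 by cameraPR). Unnamed detected rows over 1.5-fold higher on the right had a median within-side correlation of 0.526, nearer to 0.5 than to 0.01. The correlation of the listed genes themselves could not be measured, so the call depends on the preset. The cilium gene Ccdc153 had the smallest difference of the list, 1.08-fold, and Aqp1 and the tight junction gene Cldn2 were 1.58-fold and 1.88-fold higher on the right in the authors' deposited table.

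Outside the fixed list, genes singled out after their values were seen also had large folds to the right in the authors' deposited table: the coagulation factor F5 (3.23-fold), the gene listed as 1110059M19Rik (2.73-fold), the defensin Defb11 (2.55-fold), Calml4 (2.27-fold) and the prolactin receptor Prlr (1.98-fold). A total of 9 genes in the authors' deposited table were at least 2-fold higher on the right and 0 on the left, and the smallest deposited p among them was 0.0108. At 1.5-fold the counts were 37 genes on the right and 5 on the left in the authors' deposited table. Those on the left were the transporter gene Slc47a1 (1.59-fold, deposited p = 0.0308), the homeobox gene Rhox4f (1.54-fold), Prg4 (1.54-fold), Fermt1 (1.52-fold, deposited p = 0.27) and Vmn1r14 in the authors' deposited table. Of the genes in the authors' deposited table, 99.2% lay within 1.3-fold.

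**Figure D1:**
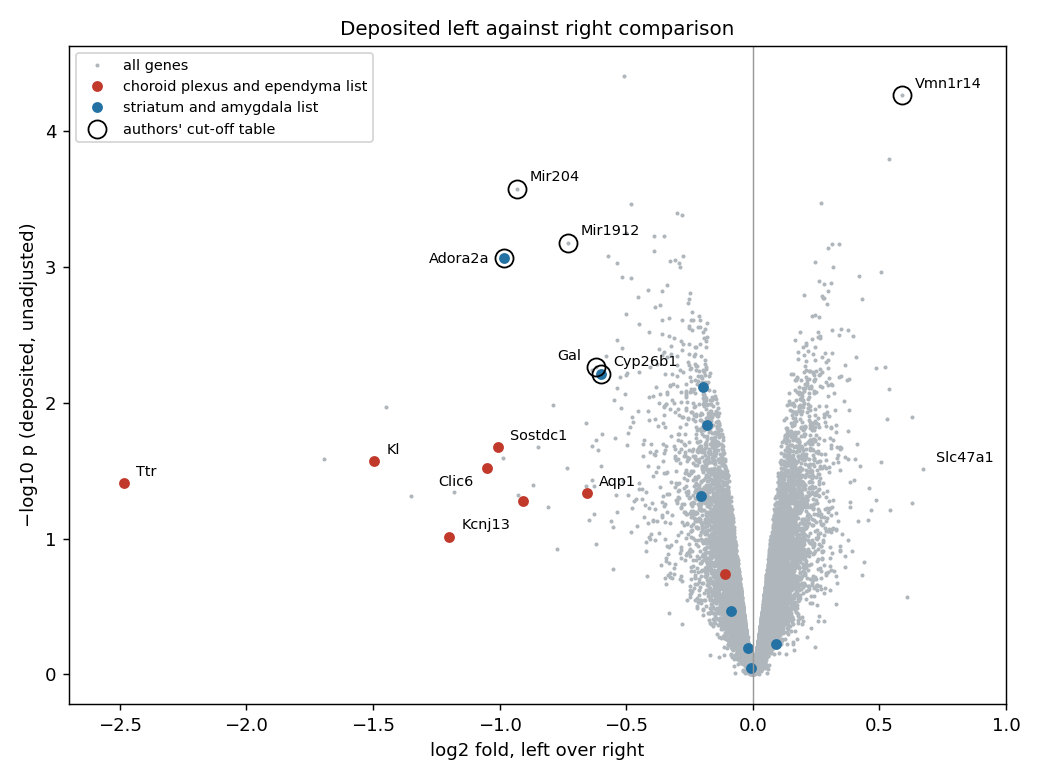
Each point is a gene of the authors' deposited table, with its log2 fold (left over right) on the horizontal axis and −log10 of its unadjusted p on the vertical axis; red and blue points are the choroid plexus and the striatum and amygdala lists, and open circles mark the authors' cut-off table. The choroid plexus genes, led by Ttr at -2.48, lie far to the right-higher side apart from Ccdc153 at -0.11, while the 6 genes of the cut-off table have smaller p-values.

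Genes of the striatum and amygdala were the other tissue group that was higher on the right. The adenosine receptor gene Adora2a, abundant in striatal projection neurons, was 1.98-fold higher on the right (deposited p = 0.000855) in the authors' deposited table. Cyp26b1, a retinoic acid degrading enzyme, was 1.52-fold higher on the right, Rgs9 1.15-fold and the tachykinin precursor Tac1 1.13-fold in the authors' deposited table. Members that differed less, named after their values were seen, were Drd1a (1.06-fold higher on the right, deposited p = 0.344), Pde10a (1.01-fold, deposited p = 0.645), Tmem90a (log2 fold -0.01) and, higher on the left, Rspo2 (1.07-fold) in the authors' deposited table. Of the 9 measured genes 8 were higher on the right, 5 had a deposited p under 0.05, 4 passed when adjusted over the list alone and 0 over all genes. The list was higher on the right than the other genes by cameraPR (adjusted p = 0.000223, median log2 fold -0.18), and the call was lost with a preset correlation of 0.2 (adjusted p = 0.0904). Adora2a and Cyp26b1 were also picked by the authors on these arrays. Without them 6 of 7 genes were higher on the right, with a median of -0.09 and a cameraPR p of 0.00508 (0.0518 with a preset correlation of 0.2).

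Ribosomal protein, interneuron, astrocyte and microglia genes were slightly higher on the right as groups. cameraPR set these lists against all genes, abundant or not. In the per-array values, detected rows leaned to the right in general, 873 against 321 at an unadjusted limma p under 0.05. Whether these lists exceed that lean was not tested. Of 29 ribosomal protein genes 25 were higher on the right, with a median log2 fold of -0.06 and Rps15 at 1.16-fold in the authors' deposited table (list adjusted p = 0.000132 by cameraPR). Of 12 GABAergic interneuron genes 9 were higher on the right, led by Tac1, the calretinin gene Calb2 (1.20-fold) and Dlx6as1 (1.12-fold) in the authors' deposited table (list median -0.08, adjusted p = 0.011 by cameraPR). Leaving out Calb2, Reln and Tac1, which other lists also hold, gave 7 of 9 genes higher on the right and a cameraPR p of 0.00639 (0.0788 with a preset correlation of 0.2). Of 10 astrocyte genes 9 were higher on the right, including Slco1c1 (1.13-fold) and the glutamate transporter Slc1a2 (1.06-fold) in the authors' deposited table (list median -0.07, adjusted p = 0.011 by cameraPR). Of 11 microglial genes 10 were higher on the right, with Trem2 at 1.07-fold and Itgam at 1.10-fold in the authors' deposited table (list median -0.05, adjusted p = 0.0174 by cameraPR). The number of genes with a deposited p under 0.05 was 1 for the ribosomal proteins, 3 for interneurons, 2 for astrocytes and 0 for microglia, and 0 in each passed when adjusted over the list alone or over all genes. All 4 calls were lost with a preset correlation of 0.2, where the cameraPR adjusted p was 0.356 for ribosomal proteins and astrocytes and 0.369 for interneurons and microglia. With the log2 fold as the statistic the calls of interneurons (cameraPR adjusted p = 0.121), astrocytes (0.281) and microglia (0.34) were lost.

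**Figure D2:**
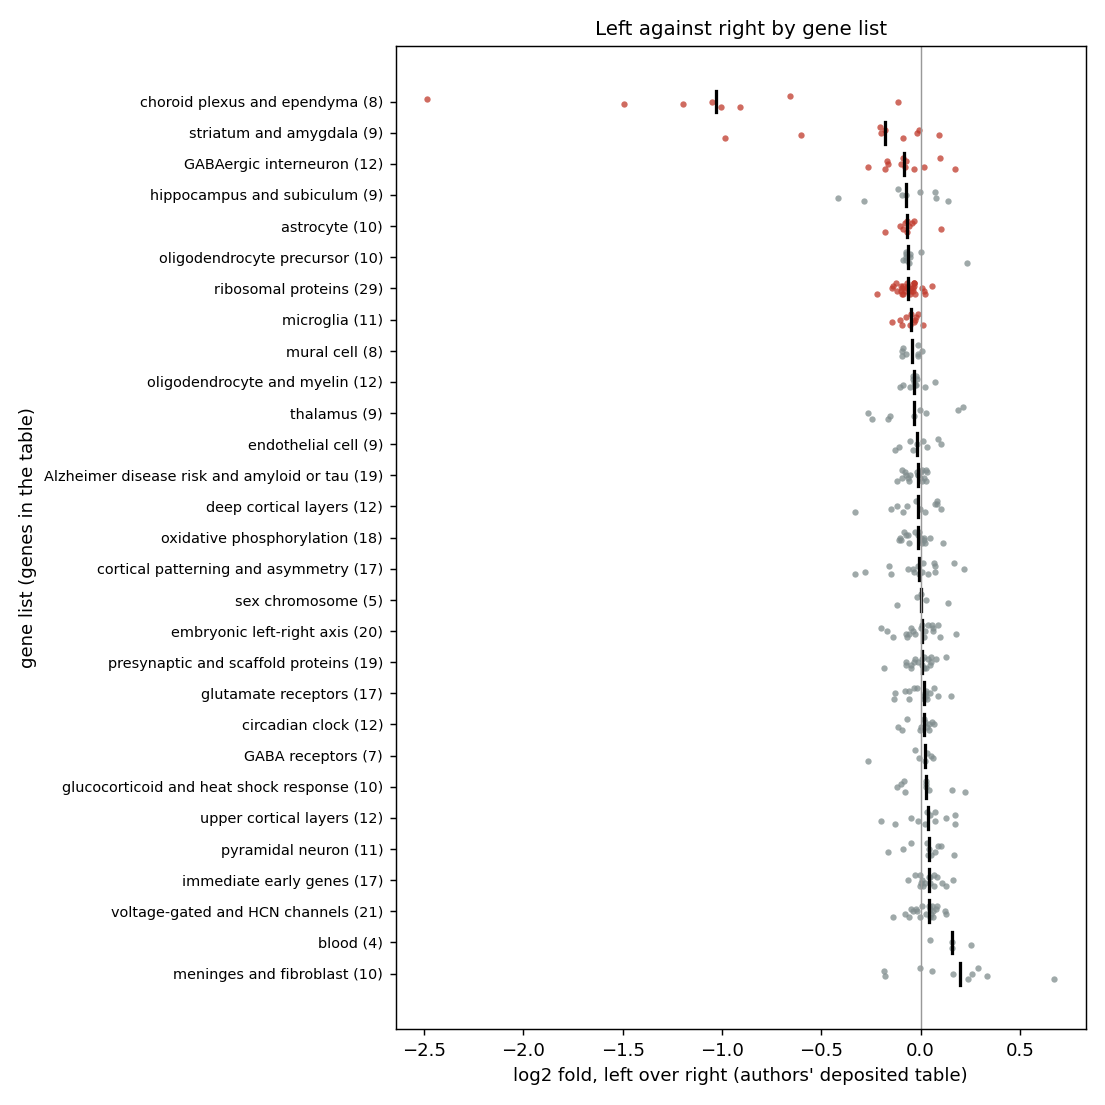
Each row is a gene list with its number of measured genes, each point a gene's log2 fold (left over right) from the authors' deposited table, and each black bar the list's median; red marks the 6 lists with a cameraPR adjusted p under 0.05 at the preset correlation of 0.01. The choroid plexus median of -1.03 lies apart from the other lists, whose medians lie between -0.18 and 0.20.

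The principal neurons and the layers of the cortex showed no list-wide difference that passed the test. The pyramidal neuron list had a median log2 fold of 0.04 over 11 genes (cameraPR adjusted p = 0.4), with the transcription factor Tbr1 1.13-fold higher on the left in the authors' deposited table. The upper layer list had a median of 0.04 over 12 genes (cameraPR adjusted p = 0.4), with Lamp5 1.13-fold higher on the left, and the deep layer list -0.01 over 12 genes (cameraPR adjusted p = 0.33), with Foxp2 1.26-fold higher on the right in the authors' deposited table (deposited p = 0.0074). Reln, a marker of EC layer 2 principal cells, was 1.13-fold higher on the left (deposited p = 0.1), Wfs1 1.05-fold (deposited p = 0.208) and Grin2b 1.05-fold (deposited p = 0.237) in the authors' deposited table. Gapdh was 1.06-fold higher on the left over the mean of its rows of the authors' deposited table (p = 0.195 from that mean). Calb1, Apoe and Actb were not analysed here.

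Genes of the embryonic left-right axis, which set body asymmetry, divided into 11 higher on the left and 9 higher on the right, with a median log2 fold of 0.00 and a cameraPR adjusted p of 0.594. Nodal was 1.04-fold higher on the left (deposited p = 0.526), and the lowest deposited p of the list was that of the cilium gene Invs, 1.10-fold higher on the right (deposited p = 0.01), in the authors' deposited table. The cortical patterning and asymmetry list had 17 genes, a median of -0.01 and a cameraPR adjusted p of 0.594. Within it Nr2f2 was 1.22-fold higher on the right (deposited p = 0.00835), the guidance receptor Robo2 1.16-fold higher on the left (deposited p = 0.0196) and Lmo4 1.05-fold higher on the left (deposited p = 0.279) in the authors' deposited table. The list of genes tied to Alzheimer disease had a median of -0.01 over 19 genes (cameraPR adjusted p = 0.121), with App 1.02-fold higher on the left and Mapt 1.01-fold higher on the right in the authors' deposited table.

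Synaptic and excitability genes differed little as groups. The cameraPR adjusted p was 0.834 for 17 glutamate receptor genes, 0.982 for 7 GABA receptor genes, 0.869 for 19 presynaptic and scaffold genes and 0.58 for 21 voltage-gated and HCN channel genes, with medians between 0.01 and 0.04. The receptor subunit Gabrg1 was 1.20-fold higher on the right (deposited p = 0.00906), and the calcium channel gene Cacna1g 1.10-fold (deposited p = 0.011), in the authors' deposited table. Of 17 immediate early genes 13 were higher on the left (median 0.04, cameraPR adjusted p = 0.191), with Ier2 at 1.09-fold in the authors' deposited table. The cameraPR adjusted p was 0.869 for glucocorticoid and heat shock genes, 0.994 for clock genes, 0.33 for oxidative phosphorylation genes and 0.869 for sex chromosome genes. For the glutamate receptor, GABA receptor, presynaptic, left-right axis and sex chromosome lists the median lay above 0 while the cameraPR direction was to the right, and the mean of all but the sex chromosome list lay below 0.

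Among other cells and neighbouring regions, the cameraPR adjusted p was 0.338 for oligodendrocyte, 0.0842 for oligodendrocyte precursor, 0.4 for endothelial, 0.218 for mural, 0.526 for hippocampal and 0.288 for thalamic genes. The meninges and fibroblast list leaned to the left, with 7 of 10 genes higher there, a median log2 fold of 0.20 and Islr at 1.26-fold in the authors' deposited table. It did not pass with the p-based statistic (cameraPR adjusted p = 0.33) and passed with the log2 fold as the statistic (cameraPR adjusted p = 8.37e-05). The thalamic gene Prkcd was 1.18-fold higher on the right (deposited p = 0.0079), and the hippocampal genes Prox1 and C1ql2 were 1.22-fold and 1.34-fold (deposited p = 0.138 and 0.189), in the authors' deposited table. The 4 measured blood genes, too few to test, were all higher on the left with a median of 0.16.

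The authors' cut-off table asked for genes with a deposited p under 0.01, and every gene in it was at least 1.5-fold different. It held 6 genes. The vomeronasal receptor gene Vmn1r14 was 1.51-fold higher on the left (deposited p = 5.43e-05) in the authors' deposited table. Higher on the right in the authors' deposited table were Adora2a, Mir204 (1.91-fold, deposited p = 0.000264), Mir1912 (1.66-fold, deposited p = 0.000661), the neuropeptide precursor Gal, encoding galanin (1.54-fold, deposited p = 0.00542), and Cyp26b1 (1.52-fold, deposited p = 0.00608). The same thresholds applied to the authors' deposited table of all genes gave 7 genes, the additional one being Mir491 (1.55-fold higher on the right, deposited p = 0.00573). After Benjamini-Hochberg adjustment over all genes the p was 0.509 for Vmn1r14 and 0.597 for the other 6. The authors chose the genes on these same arrays, so the table is not independent evidence of their direction.

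Small-p genes in the authors' deposited table included microRNA genes and genes without an established name. The smallest deposited p-values on the left after that of Vmn1r14 belonged to Mir376c (1.45-fold, p = 0.000159), 6820426E19Rik, A830025M08, Krtap6-5, Gm4701, Mir423 and Olfr969 in the authors' deposited table. On the right they belonged to Mir876 (1.42-fold, p = 3.9e-05), Mir204, Gm19938, 9930017N22Rik, Mir135a-2, Gm16495, Mir488 and Gm20326 in the authors' deposited table. Of its 20414 rows 1660 (8.13%) had a deposited p under 0.05, 777 higher on the left and 883 on the right.

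In the per-array values, whose rows are unnamed here, 0 of 41345 rows differed at an adjusted p under 0.05 by limma, the smallest adjusted p being 0.516, and an unmoderated test per row also called 0. At an unadjusted p under 0.05 limma gave 3023 rows (7.31%, against 5% by chance), 1255 higher on the left and 1768 on the right, and the unmoderated test gave 2800. Without the right 2 array the balance turned, with 1952 rows higher on the left and 1877 on the right. With quantile normalization the counts were 1558 and 1691, and with an intensity trend and robust eBayes 1167 and 2072. Of the 20672 rows with a mean above the median, 321 were higher on the left and 873 on the right at that p, and 572 and 1236 when limma was fitted to these rows alone. The row with the smallest limma p on the left, 17201337, had a log2 signal of 5.12 ± 0.04 on the left and 4.56 ± 0.08 on the right (SD, n = 3; limma adjusted p = 0.516). The row with the smallest limma p on the right, 17200641, had 3.45 ± 0.13 on the left and 4.17 ± 0.05 on the right (SD, n = 3; limma adjusted p = 0.516). Rows 17201337 and 17200641 had low mean signals of 4.84 and 3.81, under the lowest lower quartile of any array (5.80), so neither counted as detected.

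The largest difference among rows above the median signal was that of row 17348833, at 10.84 ± 2.11 on the left and 13.32 ± 0.69 on the right (SD, n = 3). Its difference of -2.48 had a 95% interval of -5.01 to 0.06 (limma adjusted p = 0.683), and the left 2 array at 13.09 was above the right 3 array at 12.52, so the sides overlapped. The largest difference to the left, in row 17263765, was 8.52 ± 0.37 against 7.85 ± 0.42 (SD, n = 3; limma adjusted p = 0.664). Differences over 1 on the log2 scale were found in 9 rows to the right and 0 to the left among rows above the median signal. For 20015 of those 20672 rows (96.8%) the 95% interval of the difference lay within 1.5-fold either way, for 99.5% within 2-fold and for 82.1% within a ratio of 5 to 4.

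**Figure D3:**
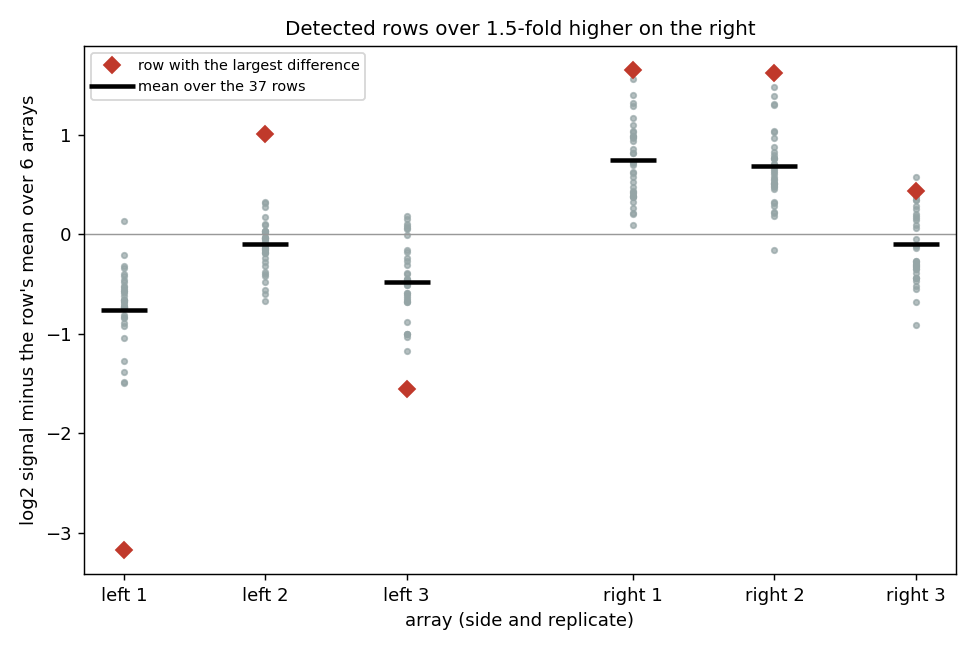
Each grey point is 1 of the 37 unnamed rows above the median signal that were over 1.5-fold higher on the right, plotted for each array as log2 signal minus the row's mean over the 6 arrays; black bars are the mean over the rows and red diamonds the row with the largest difference. The right 1 and right 2 arrays average 0.75 and 0.69, while right 3 at -0.10 and left 2 at -0.09 lie at about the same level.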

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

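The alternatives for the lists and the cut-off thresholds were chosen after the data were seen. Limma called 0 rows at an adjusted p under 0.05 in all alternatives run. The unadjusted count was 1808 when only rows above the median signal were fitted, where the fit to all rows had called 321 on the left and 873 on the right among them and this fit called 572 and 1236 (the cause was not tested), 2104 to 3829 when 1 array was left out (1952 higher on the left and 1877 on the right without right 2), and 2716 to 3249 otherwise. The lean to the right was smaller with quantile normalization, 1558 on the left and 1691 on the right, and with arrays centred on the median, 1369 and 1592. The lean was larger with an intensity trend and robust eBayes, 1167 and 2072. The number of detected rows within 1.5-fold was 19650 to 19912 when 1 array was left out, and 16964 rows lay within a ratio of 5 to 4. The replicate numbers did not meet the bar set for pairing, since not every same-numbered pair deviated together: the correlations of within-side deviations were 0.02, -0.09 and 0.05 over all rows, and 0.15, 0.01 and 0.13 over detected rows, where other pairs ran from -0.15 to 0.02. Over all rows left 1 correlated best with right 2, and over detected rows left 2 with right 3, so a shared number is a hint at most. With the replicate block, fixed or random, 0 rows passed adjustment, 2790 or 2716 passed unadjusted and 19978 or 19961 lay within 1.5-fold. The number of lists past adjustment was 5 at a preset correlation of 0.05 (microglia 0.0607), 1 at 0.2 and 0 at 0.5, because a higher preset correlation widens the error of a list's mean. It was 4 with the log2 fold as the statistic, which ended the calls of interneurons (0.121), astrocytes (0.281) and microglia (0.34) and added meninges, higher on the left. It was 7 with ranks and 6 with the smallest-p row per gene. Over these alternatives the choroid plexus list's adjusted p ran up to 0.446 and that of the striatum and amygdala list up to 0.693, while the direction stayed to the right. The authors' thresholds gave 91 genes at a fold ratio of 5 to 4, 0 at 2-fold and 0 at 1.5-fold with adjusted p, as the construction of each threshold sets. Rows with exactly 1 gene symbol, and per-array alternatives for the lists and cut-off genes, could not be run because the per-array rows are unnamed.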

Other observations

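Tests of 3 further gene lists and of gene families were chosen after the deposited results were seen, although the members of the 3 lists were written before their values were looked up. The tests on within-side correlation, on the median of all genes and on other splits of the arrays were also chosen afterwards. Of 476 microRNA genes 25 had p under 0.01 (5.25%, against 1.48% of other genes), a share given without a test because it was counted after microRNAs were seen among the smallest p-values. They went both ways, 9 higher on the left and 16 on the right. The family's median log2 fold was 0.00, and a shift of the whole family did not pass the test (cameraPR adjusted p = 0.165 over 4 families). Mir204 lies within Trpm3, a choroid plexus gene that was itself 1.28-fold higher on the right in the authors' deposited table (deposited p = 0.0331). Mir1912 lies within Htr2c and Mir491 within Focad, neither analysed here.

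Of 98 small nucleolar RNA genes 75 were higher on the right, with a median log2 fold of -0.11 (cameraPR adjusted p = 3.86e-08 over 4 families, and p = 0.0742 with a preset correlation of 0.2). Only 3 of them had p under 0.01 (Fisher's exact test, adjusted p = 0.404). Many of them have near-identical copies, so single members are uncertain. Olfactory receptor genes had 14 on the left and 1 on the right among those with p under 0.01. Their share with such a p was 1.65% against 1.58% of other genes, with no detectable excess (Fisher's exact test, p = 0.785). That comparison of shares ignores direction, and the division of 14 to 1 was not tested. Of all 908 olfactory receptor genes 372 were higher on the right, with a median log2 fold of 0.03. Of 265 vomeronasal receptor genes 3 had p under 0.01 (Fisher's exact test, p = 0.803). The cameraPR adjusted p was 0.129 for olfactory and 0.358 for vomeronasal receptor genes.

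Choroid plexus genes were higher on the right. In the deposited values a uniform shift of all genes is argued against by the median log2 fold of all genes, 0.00676. Arrays levelled before deposit would also give such a median, and a scaling difference that depends on signal was not tested. A candidate explanation is tissue carried over in dissection in amounts that differ between arrays, which stays open. The 37 rows over 1.5-fold higher on the right had a median within-side correlation of 0.526, against at most 0.2 in 100 sets of other rows matched on spread. Only 8 of the 37 rows had every right array above every left array, and in 23 left 2 was above right 3. The 37 rows were chosen for a shared direction and the matched sets were not, so part of the contrast may come from that choice. No source used here names these rows, although 8 of the 9 genes at least 2-fold higher on the right in the authors' deposited table had a row within 0.05 of their log2 fold. A second choroid plexus list had a median of -0.22, between the bounds set for and against carry-over, with 15 of 19 genes higher on the right (cameraPR p = 4.54e-07, and 0.0106 with a preset correlation of 0.2), and a motile cilia list, standing for ependymal cells, had -0.16 with 24 of 25 higher on the right (cameraPR p = 4.02e-11, and 0.00224 with that correlation). Neither list was run with a preset correlation of 0.5, which lies nearer the 0.526 of the 37 rows. Whether they exceed the lean of detected rows to the right was not tested. How many of these genes the EC itself expresses was not counted, and choroid plexus, ependyma and a difference between the sides of the EC, which was not tested, cannot be told apart.

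Striatum and amygdala genes were also higher on the right. A candidate explanation is amygdala tissue, which borders the EC, in the right samples: a second amygdala and hypothalamus list had a median log2 fold of -0.13, just past the bound set beforehand, with 24 of 27 genes higher on the right (cameraPR p = 1.89e-09, and 0.00673 with a preset correlation of 0.2). Its members with larger folds included Peg10 (1.33-fold), the neurotensin gene Nts (1.32-fold), Ngb (1.28-fold) and Dlx5 (1.17-fold) in the authors' deposited table. Crh (1.04-fold) and Otp (1.01-fold) were near even, and 3 members were higher on the left, among them Sim1 (log2 fold 0.02). The list also holds hypothalamic genes, so it does not single out the amygdala. Drd1a and Pde10a, which striatal neurons also express, were 1.06-fold and 1.01-fold higher on the right in the authors' deposited table. Striatal tissue and a difference between the sides of the EC itself stay open.

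The count of 3023 rows at an unadjusted p under 0.05 was matched or exceeded in 2 of the 10 splits of the 6 arrays, the real one included, the highest other being 4125 for left 1, left 3 and right 2 against the rest. Those arrays had lower quartiles of 5.84 to 5.86 and upper quartiles of 9.29 to 9.30. Left 2, right 1 and right 3 had 5.80 to 5.81 and 9.32 to 9.34. The spread of signal thus differed between groups that hold the sides unequally. Whether it bears on the lean of detected rows to the right was not tested. The 0 rows past adjustment were matched or exceeded in 10 of 10 splits, with 1 row in the highest other. Any split matches or exceeds a count of 0, so that share carries no information. The 20015 rows within 1.5-fold were the fewest, in 1 of 10, with 20045 in the lowest other. With 10 splits no share under 0.05 can be reached.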
